A study of Homo sapiens with 12 samples.

How the data were processed

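The arrays were Illumina HT-12 v4 bead arrays, 1 per sorted sample, hybridized with RNA of sorted cells: MSC alone, MSC from co-culture, REH alone and REH attached to MSC, with 3 arrays per group. Per the labels, 200 ng of total RNA were amplified and biotin-labelled for each array. The deposited table of unnormalized values gives, per the file headers, the mean bead intensity and a detection p-value for each of 47231 probes on each array. GenomeStudio is named for the export, per the submitters' processing notes, without a version. Between 29.0% and 31.0% of the deposited intensity values of an array were below 0, so a background had been subtracted from them. A second table, deposited as the series values, holds intensity on a linear scale for 38222 probes with array medians of 48.5 to 51.1. Its normalization method is not stated. Its columns were checked against the first table: each had its highest rank correlation with the array of the same label (0.980 to 0.988, and 0.937 at most with any other). No 2 arrays held identical values.

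From the unnormalized table, the background was estimated with nec in limma 3.58.1 (R 4.3.3) from the detection p-values, an offset of 16 was added, and the 12 arrays were quantile normalized and taken to log2. Probe names were joined to genes through the platform's annotation: 27004 probes had 1 gene, 4 had several and 20223 had none. Probes with several genes or none were not used for gene results. XIST and Y-linked genes, 126 probes, were left out of every table. No genome coordinates were used here. A gene was tested if 1 of its probes had a detection p-value below 0.05 on all 3 arrays of at least 1 group compared, and the probe with the highest mean over the 12 arrays stood for the gene. Each comparison was fitted with lmFit and eBayes on the 6 arrays compared, or on all 12 for the difference between the changes of MSC and REH. The p-values were two-sided and Benjamini-Hochberg adjusted, with 0.05 as the threshold. Where a gene was not detected on any array of a group, the fold is given as a lower bound against the lowest detected value of each array of that group.

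Gene lists (25) and marker lists (7) were tested with camera at a preset correlation of 0.01, with at least 3 tested members, Benjamini-Hochberg adjusted over the lists. An estimated correlation and fry were run beside it. The list tests of the difference between cell types were added after the data had been seen. The genes named were set by a rule: the 10 largest rises and falls among genes past the threshold whose groups did not overlap, up to 3 called members of each list or else its largest change, and 11 genes of the NF-kB pathway, the VCAM1 and CXCL12 axes and the sort. For the difference between cell types these were the 5 largest in each direction. Genes named from the fit with the replicate block, second members of lists and the marker genes of the label check were chosen after their values were seen. Uncharacterised loci and unnamed probes were counted but not named.

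The labels number the arrays of each group 1 to 3 and speak of triplicate cultures, without saying what a number shares. Whether numbers pair arrays was checked from the deviations from the group means. Same-numbered arrays correlated by 0.50 to 0.64 in MSC and by 0.40 to 0.60 in REH, all above 0.1, so the numbers were treated as pairs and the block is given where it changes a call. The pairing comes from these data, not from the labels. Replicates 1 and 2 of all groups lay on 1 chip (8 arrays, 31.1% to 32.8% of probes detected) and replicate 3 on another (4 arrays, 29.6% to 30.2%), so the chips were balanced over the groups. Positions within a chip were not balanced. Same-numbered arrays lay side by side, at A to D, I to L and E to H, with the groups in the same order each time. With groups of 3, no test for single outlying arrays was applied. The median SE of a log2 change was 0.17 in MSC (0.11 with the block) and 0.16 in REH (0.13).

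The fits were tested on simulated data with 200 changed genes, 50 at each fold. In MSC 16%, 74%, 90% and 98% of changes of 1.5-, 2-, 3- and 4-fold were recovered, with 9 false among 148 calls. In REH it was 34%, 78%, 98% and 100%, with 4 false among 159. For the difference between cell types it was 8%, 40%, 86% and 90%, with 9 false among 121. These are fits without a block, on simulated arrays without shared variation of same-numbered arrays. With 200 true changes the adjusted threshold is easier to reach than with few, so the rates may overstate recovery in the fits reported. In the real MSC fit, CCL2 missed at a fitted 2.95-fold change (limma, adjusted p = 0.655). Lists without a change gave p below 0.05 in 4.58% of 480 tests in MSC and 3.91% of 460 in REH. The simulated genes varied independently of each other, so these rates do not hold for lists whose members vary together. The NF-kB list in MSC had an estimated correlation of 0.36.

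The alternatives tried were no background correction (each array shifted so that its lowest signal was 16), median scaling, the deposited value table, normalization within a cell type, no detection filter or one at 0.01, every probe, the mean of a gene's probes, replicate or chip as a block, array weights, treat against a 1.5-fold change, all 12 arrays in the fit, 1 chip alone, and each array left out in turn. Carry-over of cells of the other type was measured on probes with a signal above 1000 in that type, and again above 2000, that were not detected in the cells sorted from monoculture.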

Results

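Gene expression was measured in 2 cell types grown apart and together. The stromal cells were human bone marrow mesenchymal stromal cells (MSC), the fibroblast-like cells that support blood formation, isolated from healthy donors. The leukemia cells were REH, an established line of precursor B acute lymphoblastic leukemia. Each of the 4 groups held 3 arrays: MSC cultured alone, MSC after co-culture, REH cultured alone, and REH that had attached to the stroma. Cultures lasted 48 h at 21% oxygen, with about 2 REH cells per MSC in co-culture. All cells were parted by flow cytometry on CD90, the product of THY1, and CD45, the product of PTPRC. Unattached REH cells of the co-cultures were discarded before the sort, whereas all cells of the REH monoculture were collected. The arrays detected 13993 to 15508 probes, or 29.6% to 32.8% of all, and the median signal per array lay between 16.8 and 19.8 intensity units. The number of arrays, 3 per group, limits the precision of each value below. The labels speak of triplicate cultures but do not tie an array to a donor, so the p-values measure the spread between these arrays.

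The sorted populations carried the transcripts of their labels. THY1 was at least 38.6-fold higher in MSC alone than in REH alone, where it was not detected (limma, adjusted p = 2.54e-11). The collagen genes COL1A1 and COL1A2 were at least 339-fold and at least 387-fold higher in MSC. In REH, DNTT, the terminal transferase of lymphoid precursors, was at least 141-fold higher, and IGLL1, a part of the surrogate light chain, at least 118-fold higher. PTPRC was dim on this array, and at least 1.28-fold higher in REH (limma, adjusted p = 0.000112). All 20 tested mesenchymal markers were higher in MSC, and 18 of 19 tested B lymphoblast markers were higher in REH. The exception was BLNK, which differed by 0.35 ± 0.20 on the log2 scale (SE, n = 3 per group; limma, adjusted p = 0.144). Of 8791 genes tested, 3688 were higher in REH and 3020 in MSC.

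The first comparison asked how stromal cells change when leukemia cells grow on them. CXCL8, which encodes the neutrophil-attracting chemokine interleukin 8, rose in co-cultured MSC by 5.06 ± 0.24 on the log2 scale (SE, n = 3 per group). That is a fitted 33.3-fold difference with a 95% interval of 22.9 to 48.4 (limma, adjusted p = 7.36e-05). CXCL8 was detected on 1 of the 3 arrays of MSC alone and on all 3 of co-cultured MSC, and with the other 2 at the lowest detected value it was at least 29.3-fold higher. SOD2, the mitochondrial superoxide dismutase, rose by 1.69 ± 0.17, a 3.23-fold difference with an interval of 2.46 to 4.24 (limma, adjusted p = 0.022). For both genes each co-culture array lay above each array of MSC alone. They were the genes past the threshold among 7775 tested, 2 up and 0 down in limma. At an unadjusted p under 0.05 there were 239 genes higher and 244 lower. Groups that did not overlap were seen for 11.6% of genes, against 10% by chance if the arrays are taken as exchangeable, which leaves out any pairing by number. CXCL8 passed with every array left out in turn. SOD2 missed the threshold without array 1 or 2 of MSC alone (adjusted p = 0.16 and 0.168) and without array 1, 2 or 3 of co-cultured MSC (adjusted p = 0.0645, 0.111 and 0.0855), and with median scaling (adjusted p = 0.054). Over 20 alternatives its log2 change lay between 1.44 and 1.91 (limma, adjusted p from 0.00126 to 0.283).

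Same-numbered arrays of MSC alone and co-cultured MSC varied together, and with the replicate number as a block 23 genes rose and 3 fell (limma), with CXCL8 and SOD2 among them. The block left each estimate as it was and lowered the SE. Of the genes that rose in the blocked fit, 9 were on the list of NF-kB targets fixed beforehand. CCL2, a monocyte-attracting chemokine, rose by 1.56 ± 0.09 (SE of the blocked fit; limma, adjusted p = 0.00458, against 0.655 without the block). TNFAIP3, which encodes the NF-kB inhibitor A20, rose by 1.55 ± 0.11. VCAM1, the vascular cell adhesion molecule, rose by 1.37 ± 0.11 (limma, adjusted p = 0.0141, against 0.597 without the block), and its 3 probes gave 1.15, 1.37 and 1.44. IL6 rose by 1.05 ± 0.11, IRF1 by 0.93 ± 0.12, IER3 by 0.77 ± 0.09, and NFKBIA, the gene of the NF-kB inhibitor alpha, by 0.91 ± 0.11. IRF1, IER3 and NFKBIA passed narrowly with the block (limma, adjusted p = 0.0474, 0.0469 and 0.0469). Without it they stood at adjusted p = 0.68, 0.201 and 0.421 (limma). Outside that list, IL32 was at least 2.23-fold and MX1, an interferon-induced antiviral gene, at least 1.82-fold higher, neither being detected in MSC alone. HES4, of the Notch-responsive HES family, rose by 0.98 ± 0.10, CCN1, a matricellular gene, by 0.78 ± 0.10, and CFB, complement factor B, by 0.74 ± 0.09. ARPC1B, a part of the actin-branching Arp2/3 complex, rose by 1.41 ± 0.12. The ribosomal RNA probe of RNA28SN5 rose by 0.89 ± 0.11 alongside these genes. The 3 that fell were POLR2L, a subunit of RNA polymerases, with -1.14 ± 0.13, NRDE2 with -0.72 ± 0.09, and an uncharacterised locus. MX1, CCN1, CFB, RNA28SN5, POLR2L and NRDE2 also passed narrowly with the block (limma, adjusted p from 0.0469 to 0.0474, against 0.126 to 0.528 without it). With the chip as a block in its place, these genes and IRF1, IER3 and NFKBIA did not pass (limma, adjusted p from 0.103 to 0.144). CCL2, TNFAIP3, VCAM1, IL32 and HES4 also missed there (limma, adjusted p = 0.103 for each), as did IL6 (adjusted p = 0.276). Of the genes named here, CXCL8, SOD2 and ARPC1B passed with the chip block (limma, adjusted p = 1.62e-05, 0.0392 and 0.0392). Without any block TNFAIP3, IL6, IL32, HES4 and ARPC1B stood at adjusted p = 0.333, 0.68, 0.149, 0.597 and 0.201 (limma).

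**Figure D1:**
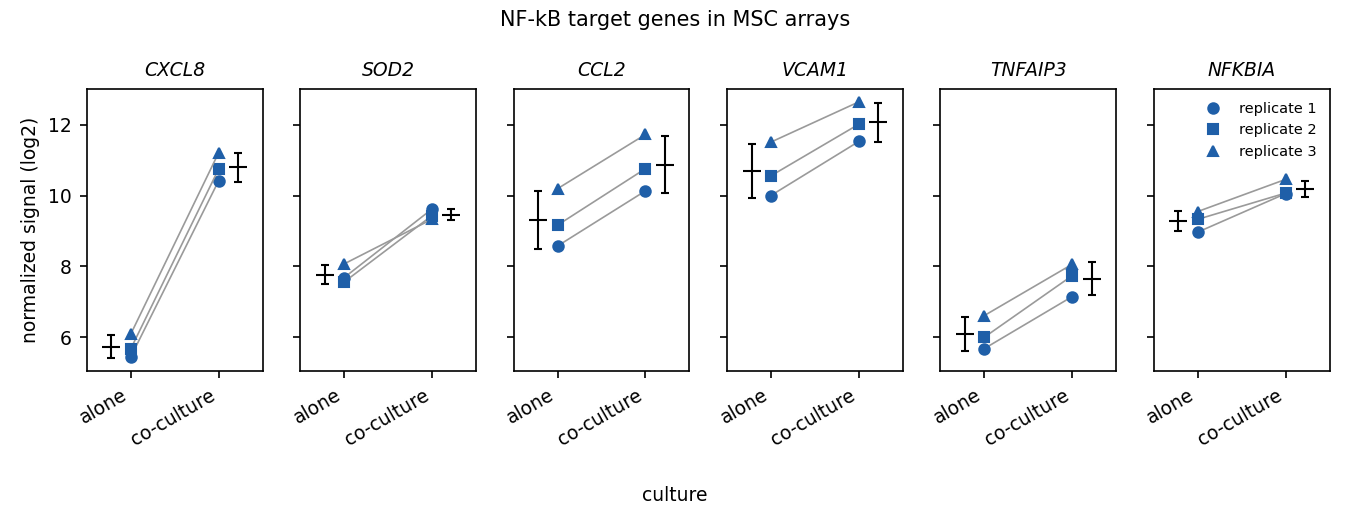
Normalized log2 signal of 6 NF-kB target genes on the arrays of MSC cultured alone and of co-cultured MSC; markers are arrays, grey lines join arrays of the same replicate number, and black bars are the group mean ± SD (n = 3). The joined lines of CCL2 and VCAM1 run nearly parallel although the arrays of a group spread widely, and CXCL8 shows the steepest rise of the 6, 5.06 on the log2 scale.

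As a list, NF-kB targets rose in co-cultured MSC. Of 19 members tested, 2 passed over all genes and 10 when adjusted over the list alone, all upward. The median change was 0.71 on the log2 scale, with 16 members above 0 (camera, adjusted p = 1.02e-11; adjusted p = 0.243 with an estimated correlation). By fry the list missed the threshold (fry, adjusted p = 0.0726). Without CXCL8 and SOD2 the median was 0.37. Without the detection filter the median was 0.17 over 31 members (camera, adjusted p = 2.53e-08). Within the chips, the medians were 0.59 and 0.74, and without background correction the median was 0.47. Median scaling of the arrays moved the median of all MSC genes from 0.00 to -0.16, and against that shift the NF-kB median was 0.69. The transcription factor gene NFKB1 changed by 0.37 ± 0.14 and RELA by 0.09 ± 0.15, or by -0.09 with median scaling, without passing (limma, adjusted p = 0.787 and 0.969). RELB was not detected in MSC alone and was detected on 2 of the 3 co-culture arrays, so it was not tested.

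The lists of secreted factors share members with the NF-kB list. Of the 5 chemokines tested, CXCL8 passed over all genes, and 3 were up when adjusted over the list alone (camera, adjusted p = 0.00187; adjusted p = 0.207 with an estimated correlation). These 3 are NF-kB targets, and without them the median of the other 2 was -0.29, so the chemokine call rests on NF-kB list members. The chemokine median was 0.71, or 0.47 without background correction. Without the detection filter the medians were 0.08 over 20 chemokines and 0.07 over 32 cytokines and growth factors (camera, adjusted p = 0.00886 for each). CXCL12, the stromal chemokine that binds CXCR4, changed by -0.17 ± 0.23 and did not pass (limma, adjusted p = 0.958), and its other probes stood at -0.15 and 0.09. All 11 cytokines and growth factors tested lay above 0, with a median of 0.29, IL32 and IL6 at the top, and LIF at 0.70 ± 0.19 (camera, adjusted p = 0.000113; adjusted p = 0.207 with an estimated correlation). None of the 11 passed over all genes and 2 were up when adjusted over the list alone. The median was 0.17 without array 3 of MSC alone and 0.19 without array 3 of co-cultured MSC. It was 0.10 within the first chip, which holds 2 of the 3 replicates, and 0.50 within the second.

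Notch targets rose as a list, with 6 of 6 members above 0 and a median of 0.49 (camera, adjusted p = 0.000214; adjusted p = 0.207 with an estimated correlation). None passed over all genes in the unblocked fit, and 4 were up when adjusted over the list alone. The receptor gene NOTCH3 stood at 0.47 ± 0.15, the ligand gene JAG1 at 0.51 ± 0.17 and HES1 at 0.87 ± 0.25. Without the detection filter the median was 0.11 over 13 members (camera, adjusted p = 0.0018). The interferon response list rose with a median of 0.22 over 14 members, of which none passed over all genes and 2 were up when adjusted over the list alone (camera, adjusted p = 0.00258; adjusted p = 0.262 with an estimated correlation). MX1 and IFIT1, at 0.82 ± 0.21, led it, while IFIT3 stood at -0.08 ± 0.19. The median was 0.15 and 0.26 within the chips, 0.14 without array 3 of co-cultured MSC and 0.13 over 30 members without the detection filter. The list that fell was that of NRF2 targets and metallothioneins, with a median of -0.17 and 11 of 14 members below 0 (camera, adjusted p = 0.00753; adjusted p = 0.243 with an estimated correlation). None passed over all genes and 1 was down when adjusted over the list alone. Within the chips the median was -0.13 and -0.25. Its lowest members were the metal-binding MT1E at -0.66 ± 0.15 and MT1X at -0.66 ± 0.19, and the list did not pass without array 3 of MSC alone (median -0.06, camera, adjusted p = 0.153).

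The other 18 lists tested in MSC did not pass camera, with adjusted p between 0.135 and 0.975. Their medians lay between -0.12 for heat shock and 0.11 for the unfolded protein response. Heat shock genes passed, downward, with the replicate block (camera, adjusted p = 0.0474; adjusted p = 0.569 with an estimated correlation), with CRYAB at -0.46 ± 0.20 as the lowest member. Cell cycle genes had a median of 0.10 and extracellular matrix genes one of 0.04, with TYMS at 0.53 ± 0.20 and FN1, fibronectin, at 0.47 ± 0.17 as the largest changes. The 14 adhesion genes tested other than VCAM1 did not pass and ran from -0.26 ± 0.15 for CD58 to 0.31 ± 0.31 for CD47, with ITGA4 at -0.16 ± 0.23 and ITGB1 at -0.08 ± 0.15. THY1, the sort marker, stood at -0.19 ± 0.16. The largest changes of the remaining lists were ADAMTS1 at 0.95 ± 0.31, CHAC1 at -0.81 ± 0.38, TAP1 at 0.67 ± 0.15, SDF2L1 at 0.65 ± 0.24, MDM2 at -0.59 ± 0.17, MYC at 0.50 ± 0.23 and ANGPTL4 at -0.49 ± 0.22, none of which passed. Smaller ones were MVD at 0.45 ± 0.15, CNN1 at -0.43 ± 0.34, VEGFA at 0.37 ± 0.20, BIRC5 at 0.33 ± 0.16, COX7B at -0.33 ± 0.30 and FOXO1 at -0.28 ± 0.15. PTPRC and CXCR4 were not detected in either MSC group. Of the B lymphoblast markers, 3 were tested in MSC and none passed, with a median of 0.17 (camera, adjusted p = 0.119, or 0.0878 with the replicate block, where 1 was up when adjusted over the list alone). The 3 monocyte and macrophage markers tested, CD14, CSF1R and CD68, lay above 0 with a median of 0.26 and did not pass (camera, adjusted p = 0.116, or 0.0724 with the block, again with 1 up over the list alone). DNTT, with a signal of 10551 in REH alone, had 12.5 in MSC alone and 22.9 in co-cultured MSC.

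The second comparison asked what attachment to stroma changes in REH cells. VCX, VCX3B and VCX3A, members of a family of X-linked genes whose usual site of expression is the male germ line, rose in attached REH. VCX was at least 1.62-fold and VCX3B at least 1.72-fold higher, with neither detected on any array of REH alone (limma, adjusted p = 0.011 and 0.015). VCX3A rose by 1.21 ± 0.16 on the log2 scale, a 2.31-fold difference with an interval of 1.81 to 2.95 (SE, n = 3 per group; limma, adjusted p = 0.0251). All 3 attached arrays lay above all 3 arrays of REH alone for each gene. The sequences of this family are near-identical, so a probe cannot be tied to a single member with certainty. Other probes of VCX3A changed by -0.15 and 0.00, and another probe of VCX3B by -0.06, all at or near background. Among 7571 genes tested, 226 were higher and 170 lower at an unadjusted p under 0.05 (limma), close to the 0.05 share that arises without any change. Groups that did not overlap were seen for 10.6% of genes, against 10% by chance if the arrays are taken as exchangeable. Past the adjusted threshold, 3 genes rose and 0 fell (limma). The count was 0 without array 1, 2 or 3 of REH alone or array 2 of attached REH, 1 without array 3 of attached REH and 2 without its array 1. No gene passed with the deposited value table, or with median scaling in place of quantile normalization.

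With the replicate number as a block, 4 genes rose and 2 fell in attached REH (limma). The addition upward was GIMAP4, a GTPase gene of lymphocytes, with 1.13 ± 0.13 (SE of the blocked fit; adjusted p = 0.0164, against 0.361 without the block). The 2 that fell were the small nuclear RNA genes RNU1-3, at 0.498-fold, and RNVU1-7, at 0.548-fold, both of the U1 splicing RNA (limma, adjusted p = 0.0318 and 0.0491). Without the block these stood at adjusted p = 0.056 and 0.177.

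**Figure D2:**
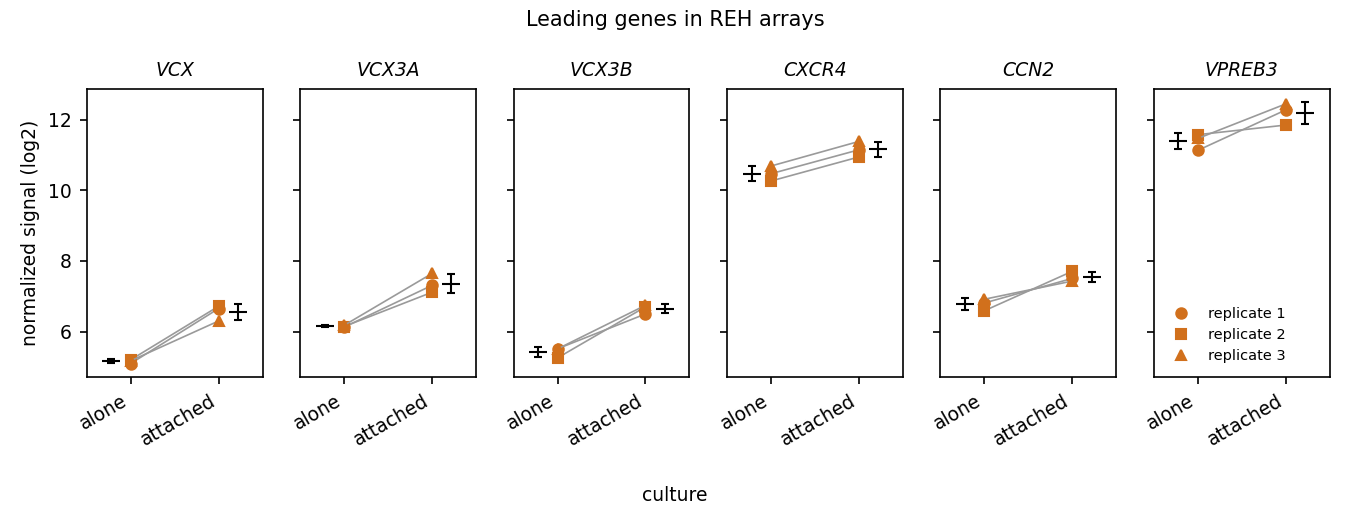
Normalized log2 signal of 6 genes on the arrays of REH cultured alone and of attached REH; markers are arrays, grey lines join arrays of the same replicate number, and black bars are the group mean ± SD (n = 3). VCX, VCX3A and VCX3B passed the threshold, while CXCR4, CCN2 and VPREB3, with changes of 0.69, 0.78 and 0.80, did not.

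Lists that rose in attached REH were led by genes that did not pass on their own. The precursor B cell program had 14 of 16 members above 0 and a median of 0.16 (camera, adjusted p = 0.0139; adjusted p = 0.388 with an estimated correlation). The full list shares 13 genes with the B lymphoblast markers, which as a list did not pass in REH (median 0.06; camera, adjusted p = 0.427). The largest change in the precursor B cell program was that of VPREB3, a protein of the precursor B cell receptor, at 0.80 ± 0.19. Adhesion receptors and ligands had a median of 0.07 over 11 members (camera, adjusted p = 0.0139; adjusted p = 0.388 with an estimated correlation). That median was 0.17 without array 1 of attached REH or array 3 of REH alone and 0.12 without array 2 of REH alone. The call was lost without array 2 or 3 of attached REH (median 0.14 and 0.10; camera, adjusted p = 0.0765 and 0.0543). CXCR4, the receptor for CXCL12, stood at 0.69 ± 0.17 (limma, adjusted p = 0.441), with a second probe, detected on all REH arrays, at 0.35, and the integrin genes ITGA5 at 0.51 ± 0.20 and ITGB2 at 0.47 ± 0.15. The subunits of the VCAM1-binding integrin VLA-4, ITGA4 and ITGB1, both stood at 0.29, with SE 0.18 and 0.14 (limma, adjusted p = 0.998 and 0.978). Matrix proteases and their inhibitors had 7 of 7 members above 0 and a median of 0.25, with PLAUR, the urokinase receptor, at 0.67 ± 0.20 (camera, adjusted p = 0.00965; adjusted p = 0.529 with an estimated correlation). A second probe of PLAUR, detected on 2 arrays of attached REH and on none of REH alone, stood at 0.31. TGF-beta and YAP targets rested on 3 members, with CCN2 at 0.78 ± 0.15 and ID2 at 0.06 ± 0.18 (camera, adjusted p = 0.0283; adjusted p = 0.388 with an estimated correlation; adjusted p = 0.0763 with the replicate block). That list passed under 3 of 12 alternatives, and its call was lost in the deposited value table. CCN2 is also on the list of mesenchymal markers, of which 7 were tested in REH with a median of 0.03 (camera, adjusted p = 0.0691). Of these 7 markers, 4 lay above 0 and 3 below, and 2 were up when adjusted over the list alone. Within the first and the second chip the median was 0.19 and 0.09 for the precursor B cell program, 0.11 and 0.13 for adhesion, 0.37 and 0.24 for proteases and 0.15 and 0.51 for TGF-beta and YAP targets. None of the members of these 4 lists passed over all genes. Without the detection filter the medians were 0.01 over 22 proteases and inhibitors, 0.00 over 23 adhesion genes and 0.02 over 18 TGF-beta and YAP targets, and these 3 calls were lost (camera, adjusted p = 0.458 for each). The precursor B cell list passed there, with a median of 0.10 over 20 members (camera, adjusted p = 0.0139). Adjusted over the list alone, 1 precursor B cell gene, 2 adhesion genes, 1 protease gene and 1 TGF-beta target were up.

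The lists of cholesterol synthesis, MYC and ribosome biogenesis and p53 targets fell in attached REH. All 13 cholesterol synthesis genes tested lay below 0, with a median of -0.20 and HMGCS1 at -0.48 ± 0.23 (camera, adjusted p = 0.00815; adjusted p = 0.529 with an estimated correlation). The call was lost without array 2 or 3 of attached REH (median -0.08 and -0.17; camera, adjusted p = 0.187 and 0.0544) and without array 1 of REH alone (median -0.16, adjusted p = 0.301). MYC and ribosome biogenesis genes had 14 of 17 members below 0 and a median of -0.08, with the nucleolar NOP16 at -0.50 ± 0.17 and MYC itself at -0.07 ± 0.15, or -0.32 by its second probe (camera, adjusted p = 0.0151; adjusted p = 0.388 with an estimated correlation). The p53 targets had 8 of 9 members below 0 and a median of -0.13, with TIGAR at -0.38 ± 0.14 (camera, adjusted p = 0.0416; adjusted p = 0.529 with an estimated correlation; adjusted p = 0.0547 with the replicate block). The MYC median was -0.05 without array 1 and -0.16 without array 2 of REH alone, and the p53 median -0.31 without array 3 of attached REH. Within the first and the second chip the medians were -0.14 and -0.23 for cholesterol synthesis, -0.04 and -0.16 for MYC and -0.28 and -0.11 for p53. Without the detection filter the MYC list did not pass (median -0.07 over 18 members; camera, adjusted p = 0.0561). No member of these 3 lists passed over all genes or when adjusted over the list alone. Of the 7 lists called in REH by camera, 0 were called without array 2 or array 3 of attached REH, 3 without array 1 and 5 without array 3 of REH alone, and 5 without array 1 of attached REH. The MYC and p53 lists were lost without that array (camera, adjusted p = 0.0733 and 0.372), while 3 lists not called before passed.

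The other 16 lists tested in REH did not pass camera. NF-kB targets had a median of 0.03 over 17 members, or -0.05 with median scaling, with none past the threshold (camera, adjusted p = 0.981). Among them were BCL3 at 0.71 ± 0.19, CXCL8, at least 1.10-fold lower in attached REH, where it was not detected, NFKB1 at 0.16 ± 0.16 and NFKBIA at 0.03 ± 0.15, or -0.05 with median scaling. RELA stood at 0.10 ± 0.16, or at -0.01 in the deposited value table. Cell cycle genes had 27 of 34 members above 0 and a median of 0.08 (camera, adjusted p = 0.191), with MCM6 at 0.32 ± 0.15. NRF2 targets and metallothioneins had a median of -0.09 (camera, adjusted p = 0.0863), with the quinone reductase gene NQO1 at -0.96 ± 0.18 (limma, adjusted p = 0.187). EDEM1 of the unfolded protein response stood at 0.78 ± 0.16, ACTA2 at -0.58 ± 0.18, PIM1 at 0.53 ± 0.39, COL5A1 at 0.40 ± 0.18 and PFKFB3 at 0.39 ± 0.20, none of which passed. A second probe of PFKFB3, detected on all REH arrays, stood at -0.02. Smaller ones were PSAT1 at 0.30 ± 0.17, HLA-DRA at 0.29 ± 0.14, PLIN2 at 0.26 ± 0.17, ATP5MC3 at -0.25 ± 0.17, HSPB1 at 0.24 ± 0.16, ISG15 at -0.19 ± 0.16 and NOTCH1 at 0.14 ± 0.16. IL15 stood at -0.23 ± 0.16, or at 0.04 in the deposited value table. DUSP6 stood at -0.35 ± 0.30, its second probe at 0.36 and the mean of both at 0.01. PTPRC, the sort marker, stood at -0.27 ± 0.15, and VCAM1, CXCL12 and THY1 were not tested in REH. Chemokines and cytokines had 2 tested members each in REH, too few for a list test. The B lymphoblast markers had a median of 0.06 over 19 members (camera, adjusted p = 0.427). COL1A2, with a signal of 22548 in MSC alone, had 28.0 in REH alone and 43.9 in attached REH.

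**Figure D3:**
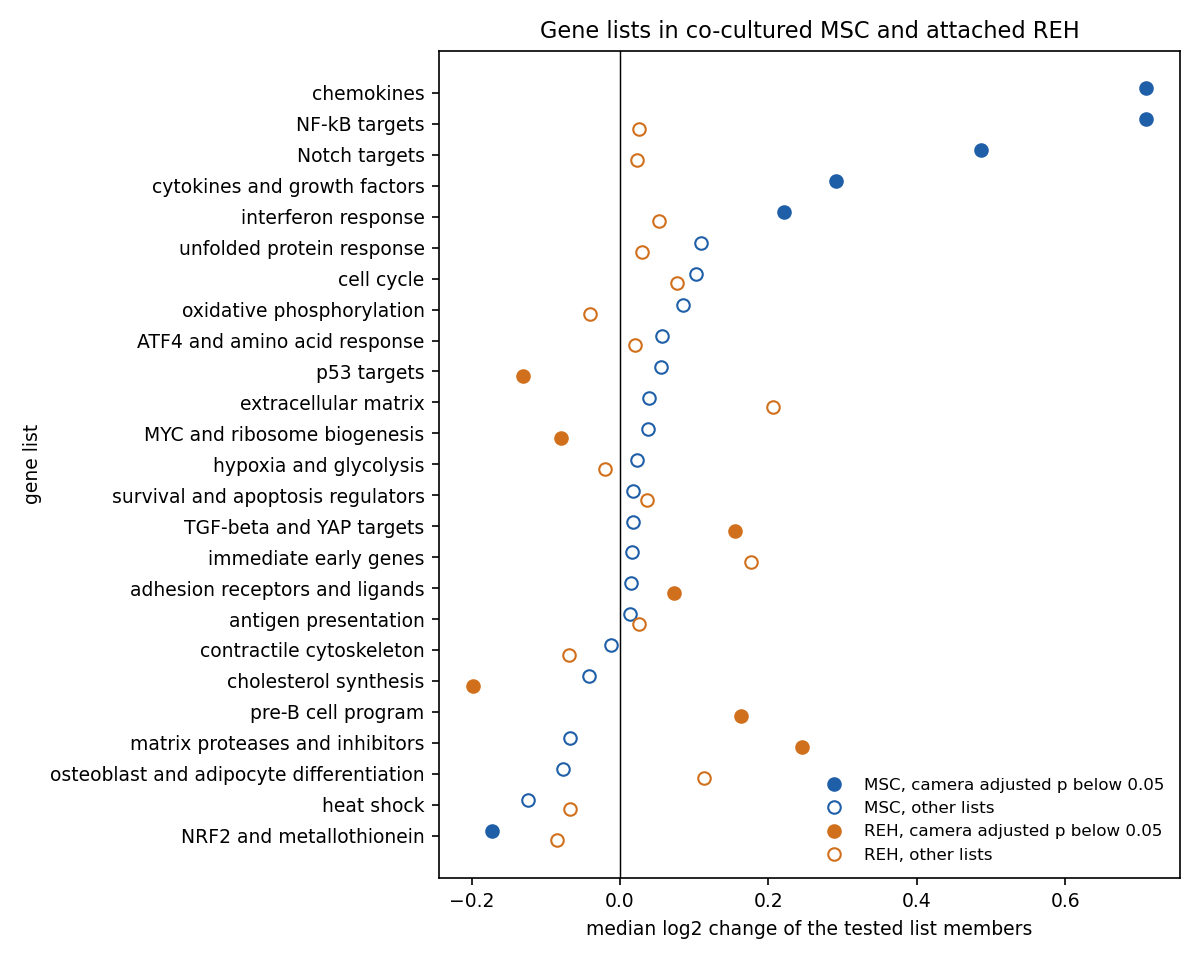
Median log2 change of the tested members of each gene list, in co-cultured MSC against MSC alone (blue) and attached REH against REH alone (orange); filled points are lists with a camera adjusted p below 0.05 at the preset correlation, and lists with fewer than 3 tested members are left out. NF-kB targets and chemokines lie at 0.71 in MSC, and cholesterol synthesis lies lowest in REH at -0.20.

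The title of the series speaks of reciprocal activation, so the changes of both cell types were set against each other in a fit of all 12 arrays. Co-cultured MSC and attached REH are both sorted from co-cultures, so their arrays may share cultures, which the fit without a block leaves aside. The change of CXCL8 in MSC exceeded that in REH by 5.56 ± 0.29 on the log2 scale, and that of SOD2 by 1.79 ± 0.26 (SE, n = 3 per group; limma, adjusted p = 1.43e-07 and 0.019). CXCL8 was not detected in attached REH, so its value is a fitted one. IL32 also passed (adjusted p = 0.0404), but was detected in co-cultured MSC alone of the 4 groups, so no size is given. Over 23 alternatives the difference passed under all for CXCL8, under 12 for SOD2 and under 5 for IL32, which missed with the chip as a block (limma, adjusted p = 0.0581; 0.00383 to 1.00 over the alternatives). NF-kB targets as a list moved further up in MSC than in REH, with a median difference of 0.37 over 22 members, of which 2 passed over all genes and 8 were up and 1 down when adjusted over the list alone (camera, adjusted p = 2.37e-11). With an estimated correlation the adjusted p was 0.0615, and with the replicate block as well it was 0.0321. LBH changed lower in MSC than in REH, by -1.26 ± 0.19 (limma, adjusted p = 0.0228). VCX, VCX3B, the long non-coding RNA LINC00667 and an uncharacterised locus also passed in that direction (limma, adjusted p = 0.0146, 0.019, 0.0404 and 0.0404). Each of these 4 was undetected in at least 2 of the groups, so no size is given. LBH, a transcription cofactor gene, stood at -0.75 in MSC and 0.51 in REH, and a second probe of it at 0.31 and -0.12, near background. The ribosomal RNA probe of RNA28SN5 differed by 1.25 ± 0.21. Of 23 alternatives, VCX passed under 14, LBH and VCX3B under 11, RNA28SN5 under 8 and LINC00667 under 6. In all, 9 of 9092 genes passed, 4 upward and 5 downward, and 11 upward and 10 downward with the replicate block (limma).

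Chemokines (adjusted p = 0.000282), cytokines and growth factors (adjusted p = 1.95e-05) and Notch targets (adjusted p = 0.000407) were also further up in MSC than in REH by camera, each with an adjusted p of 0.0393 with an estimated correlation. With the replicate block as well, that adjusted p was 0.179, 0.179 and 0.216. Interferon response, cholesterol synthesis and MYC and ribosome biogenesis genes passed upward at the preset correlation (camera, adjusted p = 0.0286, 0.0198 and 0.014), and not with an estimated correlation, where the adjusted p was 0.375, 0.592 and 0.124. Interferon response was lost with the replicate block (camera, adjusted p = 0.0696). No gene passed in both cell types: 6254 genes were tested in both, of which 2 passed in MSC and 0 in REH (limma), so no overlap could arise. Across those genes, which are not independent replicates, the changes in MSC and REH correlated with Pearson's r = 0.10 and Spearman's rho = 0.12.

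**Figure D4:**
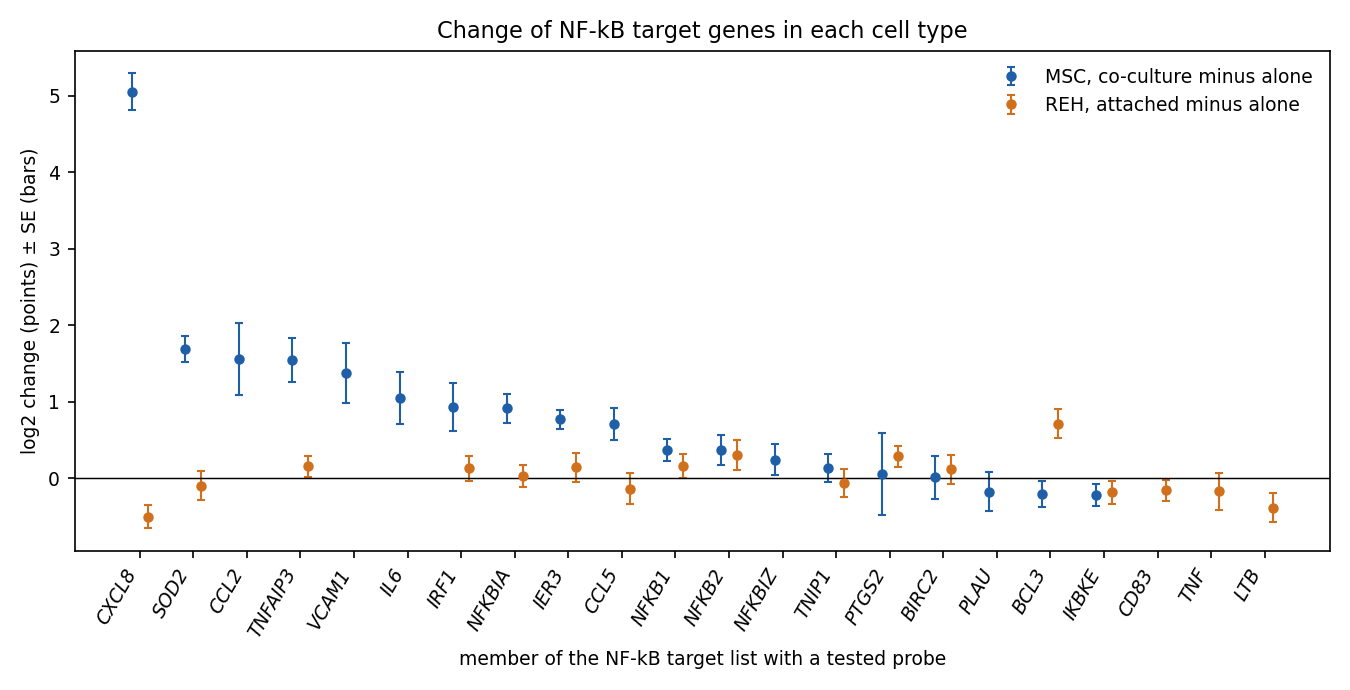
Log2 change ± SE (bars) of each tested NF-kB target in MSC (co-culture minus alone, blue) and in REH (attached minus alone, orange), with 3 arrays per group; a missing point is a gene not tested in that cell type. CXCL8 stands at 5.06 in MSC, its REH point rests on attached arrays without detection, and 16 of the 19 MSC points lie above 0.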

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

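The tests of carry-over, chips, normalization, near-identical probes and same-numbered arrays, and the grouping of the splits by pairs and chip, were chosen only after the results were seen, while the splits of the arrays were chosen before the data were examined, as were the gene lists, the comparisons and the alternatives to the processing other than those named below.

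Several genes changed differently in the 2 cell types by a test of the difference itself (limma, 9 of 9092 genes). The fitted change in MSC minus that in REH was 5.56 for CXCL8, 1.79 for SOD2, 1.52 for IL32, 1.25 for RNA28SN5, -1.06 for LINC00667, -1.20 for an uncharacterised locus, -1.23 for VCX3B, -1.26 for LBH and -1.37 for VCX on the log2 scale. Those of SOD2, RNA28SN5 and LBH rest on genes detected in all 4 groups. The others rest on at least 1 group without detection, so their fitted values are not measured sizes. Of 100 splits of the arrays within the cell types, 2 gave as many genes, the real one included (9 genes in the real split, 163 at most in another). Most of these splits leave at least 1 pair of same-numbered arrays on the same side. Of the 18 that part all 3 pairs in both cell types, as the real one does, it gave the most genes, 4 at most in another, and 18 are too few for a share under 0.05. The split with 163 genes points to a structure of the arrays that was not identified: it put the arrays of the second chip together in both cell types, but the 15 other splits that did so gave 0 genes in limma. With the chip as a block the count was 10 and with the replicate number as a block 21.

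Probes without a gene name, which enter no comparison of genes, also held a signal. Of 3355 such probes among 12899 tested in MSC, 2 rose in co-culture (limma, adjusted p = 0.00114 and 0.0103). The first rose by 2.95 ± 0.19 on the log2 scale. The second was not detected in MSC alone or in either REH group and was at least 2.01-fold higher, with a fitted value of 1.82 that is not a measured size. In REH, 0 of 3331 unnamed probes passed in limma.

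The first pattern weighed is the rise of NF-kB targets in co-cultured MSC. REH cells left in the sorted MSC were tested on 2 parts of the list. The 11 members lower in REH than in MSC, which added REH cells would lower, had a median of 0.24 (95% bootstrap interval 0.01 to 1.05). That interval resamples genes of the same arrays as if they were independent, so it measures no spread between cultures and decides nothing by itself. The 8 members higher in REH would need a median of 38.0% of REH signal, against 0.701% at most over 41 REH-specific probes. The chips were balanced over the groups, so a constant difference between them cancels in the change. The lower of the medians within a chip, 0.59, was therefore no test of such a difference. The normalization over both cell types was argued against by the lowest median under 3 other normalizations, 0.53. A biological response of the stroma to leukemia cells may underlie the rise, as a hypothesis found and tested on the same data. Soluble factors and contact were not told apart, as the groups compared differ in both. For the count of genes changed in MSC, 1 of 10 splits, the real one, gave as many genes (2 in the real split, 0 at most in another), and 10 splits are too few for a share under 0.05.

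The second pattern is the rise of VCX, VCX3A and VCX3B in attached REH. MSC RNA carried over was argued against by the levels in MSC alone, the nearest of which lay below attached REH by 1.47 on the log2 scale (-1.47). Whether 1 transcript was read by probes of near-identical genes, or several transcripts rose, cannot be told apart. The 3 fitted changes differed by at most 0.19, but VCX and VCX3B were not detected in REH alone, so this difference decides nothing. Attached cells were compared with all cells of a monoculture, so selection of cells that attach stays open beside a response to the stroma, and neither was tested. For genes changed in REH, 1 of 10 splits, the real one, gave as many genes (3 in the real split, 0 at most in another), again too few splits for a share under 0.05.

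The third pattern is that arrays of the same number varied together. For numbers 1 and 2, both on the first chip, a difference between the chips as the whole cause was argued against by arrays of that chip with other numbers, which correlated on average by -0.103 in MSC and 0.0341 in REH, below the lowest same-number values of 0.503 and 0.404. These are correlations of deviations from means of 3 arrays, which lowers those of other numbers when same-numbered arrays vary together. Arrays of different chips correlated lower still, by -0.372 and -0.379 on average, so the chip may add to the pattern. The arrays numbered 3, which correlated by 0.644 in MSC and 0.598 in REH, are all of the second chip, so number and chip cannot be told apart for them. Same-numbered arrays also lay side by side on a chip, so number and position cannot be told apart for any number. A shared day, donor or thaw of cells behind each number may also be a source, and no label settles it. Among the 4 splits that part all 3 pairs, the real one gave 26 genes in MSC and 6 in REH with the replicate block, and the others 0 at most. These 4 splits are too few for a share under 0.05. For MSC against REH cultured alone, 1 of 10 splits, the real one, gave as many genes (6708, and 0 at most in another), too few for a share under 0.05.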

How the results depend on the processing

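The list tests without single members were chosen only after the result was seen, and all other alternatives were planned. Of 2312 values of 118 genes and lists under alternatives, 2053 kept their direction and their side of the threshold, 193 were weaker, 53 stronger and 13 reversed. Most of the genes had not passed in the fit reported, and for them keeping their side means only that they again did not pass. All 193 weaker values are lost calls of genes and lists that had passed, so the pooled count does not measure how stable the calls were.

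Genes changed in MSC numbered 2, and 1 with median scaling, no detection filter, the mean of probes, treat or 1 chip alone, 4 with every probe and 12 with all 12 arrays in the fit. Genes changed in REH numbered 3, and 0 with median scaling, the deposited table, no detection filter, every probe, treat or 1 chip alone (limma, 396 at an unadjusted p under 0.05 in the fit reported), and 5 with all 12 arrays. Genes whose change differed numbered 9, and 5 without background correction, 2 with median scaling or the deposited table, and 1 with treat. Lists called were 6 in MSC and 7 in REH at the preset correlation, 0 and 0 with an estimated correlation, 2 and 0 with fry, and 3 in REH without a detection filter (cholesterol synthesis, p53 targets and the precursor B cell program). The 2 called by fry in MSC were chemokines and the ATF4 and amino acid response (fry, adjusted p = 0.00488 for each). The latter was not called by camera (adjusted p = 0.696), and NF-kB targets missed by fry (adjusted p = 0.0726). Leaving out 1 array at a time gave 1 to 2 genes in MSC, 0 to 2 in REH, 1 to 9 for the difference, and 6 to 7 lists in MSC and 0 to 8 in REH. Each of these fits lacked 1 array, so the range of lists in REH depended on which array was left out. It was 0 without array 2 of attached REH and 8 without array 1 of attached REH. The cause of these differences was not tested. CXCL8 passed in MSC under all alternatives (adjusted p from 5.51e-09 to 0.0136). SOD2 passed under 10 of 20 alternatives, VCX under 10, VCX3B under 9 and VCX3A under 7. The count of 0 genes passing in both cell types says nothing on stability, since REH had 0 calls among the 6254 shared genes in the fit reported (limma).

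With the replicate block, which pairs same-numbered arrays, 26 genes passed in MSC, 6 in REH and 21 for the difference. At the preset correlation it kept the 6 lists of MSC and added heat shock, ended the calls of TGF-beta and YAP targets and of p53 targets in REH and of interferon response for the difference, and changed no other list call.

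The chemokine list in MSC, at 0.71, turned to -0.29 without the members of the NF-kB list, which left 2 members. The other reversals were of changes that had not passed: ITGA4 in MSC with array weights (0.0054) and on 1 chip (0.11), RELA in MSC with median scaling (-0.087), DUSP6 in REH with the mean of probes (0.0053), IL15 in REH in the deposited table (0.037), NFKBIA in REH with median scaling (-0.049) and on 1 chip (-0.048), and RELA in REH in the deposited table (-0.010). With 1 array left out, CXCL12 in MSC ran from -0.39 to 0.031, NFKBIA in REH from -0.044 to 0.097 and RELA in REH from -0.018 to 0.22. Their cause was not tested. Signals near background, with a median of 16.8 to 19.8 per array, limit dim genes.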

Other observations

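The test of correlated changes was chosen only after the result was seen, while the list of FOXO targets was fixed before its values were seen.

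Several genes known as FOXO targets or linked to quiescence stood high in attached REH without passing: KLHL24 at 0.74 ± 0.15, YPEL3 at 0.74 ± 0.17 and TSC22D3, at least 1.32-fold higher by a probe not detected in REH alone (limma, adjusted p = 0.229, 0.339 and 0.593). Other probes of TSC22D3, of which 1 was detected on 1 array of REH alone, stood between -0.01 and 0.30. The hypothesis that FOXO activity may rise on attachment was tested on other FOXO targets, with these genes left out. The 14 tested of 20 had a median of 0.08, with 10 above 0 (camera, p = 0.333, and 0.362 with an estimated correlation). IL7R was highest at 0.43 and BCL6 lowest at -0.33. The hypothesis was not borne out by this list.

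The change of LBH differed between the 2 cell types, at -0.75 in MSC and 0.51 in REH, neither of which passed (limma, adjusted p = 0.372 and 0.593). The hypothesis that genes rising in attached REH tend to fall in co-cultured MSC was tested across 6254 genes. The changes correlated by r = 0.10, above 0, so across all genes they did not run in opposite directions. Co-cultured MSC and attached REH may share cultures, which could raise r. Nearly all of these genes did not pass in either cell type, so r decides nothing on the genes that rise in attached REH. Genes are not independent replicates.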
